A study of Mus musculus with 16 samples.

How the data were processed

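The starting point was the table of raw read counts per gene, as deposited by the authors, for 16 libraries of mouse hematopoietic stem cells. The counts were made by the authors from aligned reads and, as deposited, carried no normalization. The submitters' notes name STAR 2.5.2b, featureCounts, Subread 1.5.1 and the mouse genome build mm10, without giving the order or the role of each. The strand used for counting and the gene annotation are not given in the sources used here, so counts of genes that overlap another gene or have close paralogs carry an uncertainty of unknown size. The table held 14829 genes followed by 2504 empty lines. Every gene in it exceeded 0.5 CPM (counts scaled to library size) in at least 2 libraries, so genes with lower counts had been removed before the table was made. The values were whole numbers and each column was matched to a sample by its name, with 0 columns left unmatched. Genome positions are those in the table, on build mm10.

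Library totals ran from 12960704 to 19226963 counts. A count of 0 in 1 library, read as up to 3 counts, allows a level of up to 0.156 to 0.231 CPM depending on the library. These limits cover counting error only, since reads without molecular identifiers are not independent molecules.

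Samples were grouped by age and treatment into 4 groups of 4 libraries. The libraries came from 8 separate mice, 4 young and 4 old, and the cells of each mouse were divided into a vehicle and a dmPGE2 library. The sample descriptions carry 2 consecutive dates, with 2 young and 2 old mice on each. These are called date 1 and date 2, and the sources used here do not say which step was done on them. The comparisons, their tests, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined.

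Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (robust dispersion, TMM scaling, filterByExpr) in R 4.3.3, and called at a Benjamini-Hochberg adjusted p under 0.05. For dmPGE2 against vehicle, all 16 libraries entered 1 fit with mouse as a block and separate dmPGE2 terms for old and young mice, which left 6 residual degrees of freedom and 13942 genes. The pairing comes from the labels, since both libraries of a pair hold cells of the same mouse. After removal of the group means, vehicle and dmPGE2 libraries of a mouse correlated at 0.324 to 0.566, and after removal of group and date means at -0.000528 to 0.146, so most of that correlation went with date. Without the replicate block, and so without any adjustment for date, the count for all mice was 39 in place of 85. A fit with date but without mouse was not run, so this fall cannot separate pairing from date. The average of the dmPGE2 terms gave the response of all mice, and their difference gave the age by dmPGE2 interaction. Old against young mice was tested in the 8 vehicle libraries (13369 genes) and in the 8 dmPGE2 libraries (13279 genes), each with a term for date and 5 residual degrees of freedom. Errors of log2 fold changes are approximate standard errors. They were taken as the absolute log2 fold change over the square root of the F statistic of the quasi-likelihood test. Errors of CPM values are SD over the mice of a group.

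The 26 fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison. camera with an estimated correlation and fry were run beside it, except for the lists within a date alone, which were tested at the preset correlation only. Within the 6 comparisons, the calls that held with an estimated correlation were those of genes known to be higher in aged stem cells in both age comparisons and of platelet genes in the dmPGE2 arm. With fry, most list calls of the age comparisons held. The mitochondrially encoded list had no member to test and was not analysed here. No list called in the 6 comparisons had a median, mean and test that differed in sign. Among lists not called they differed in all mice for the prostaglandin, Wnt, homing, interferon and stem cell identity lists, and in both age comparisons for the Wnt, apoptosis and endothelial lists. Lists with under 5 tested members would have been given as values only.

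A named gene had an adjusted p under 0.05, a mean log2 CPM of at least 2 and either the same direction in every mouse (dmPGE2) or no overlap between the groups (age). The rule took the 8 largest rises and the 8 largest falls of each comparison, with up to 4 called members of each list by smallest p, whatever their level or overlap. For the interaction it took the 3 smallest p. The genes Ptger1, Ptger2, Ptger3, Ptger4, Cxcr4, Birc5, Ccnd1, Ptgs2, Nr4a1, Crem, Fos, Slamf1, Selp and Vwf were always given. Predicted genes were counted but not named. Some genes that the rule or the comparison of the dates would give are not reported here. Genes named in the comparison of the dates were taken from the largest differences, or as well-known markers, after their values were seen.

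The shift along the age difference was computed per mouse as the mean paired log2 change of 100 genes higher in old mice minus that of 100 genes lower in old mice. The 200 genes were ranked in the 4 vehicle libraries of the other date, so that no library of a mouse entered its own ranking. It was tested with a two-sided exact sign-flip permutation test. Log2 CPM used a prior count of 0.5, and principal components used a prior count of 2.

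The alternatives chosen beforehand were DESeq2 size factors, no filter, a stricter filter (5 CPM in 4 libraries), the Wald test of DESeq2 1.42.0, limma-voom, dispersion without the robust option, libraries thinned to the lowest total, each date alone, no replicate block, each age fitted alone, no date term in the age fits, all 16 libraries in 1 age fit and leaving out each mouse. A fit with a dmPGE2 term for each date and age, with mouse as a replicate block and 4 residual degrees of freedom, was chosen after seeing the data, as were the date-wise values of the correlation, the shift and the lists. Other groupings of the same libraries were fitted for each count. The procedure was also tested on simulated data with known changes. With 2-fold changes it recovered 85.1% of the changed genes in all mice, 77.6% in old mice, 79.1% in young mice, 58.2% for the interaction, 80.6% for age under vehicle and 85.1% for age under dmPGE2. Among unchanged genes it called 16, 12, 11, 3, 11 and 14 in the same order. Simulated changes were the same in every mouse that had them, unlike the measured dmPGE2 effects, and spared genes with low counts. For age, the simulated spread came from the fit with mouse as a block, which leaves out differences between mice. These shares may therefore be too high.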

Results

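RNA was measured in hematopoietic stem cells, the blood-forming stem cells of the bone marrow, sorted from young and old mice. Bone marrow was held for 1 hour at 37 °C with dmPGE2, a long-acting dimethyl analogue of prostaglandin E2, or with vehicle. The cells of 8 separate mice gave 16 libraries in 4 groups of 4, with a vehicle and a dmPGE2 library from each mouse. Library totals averaged 15.9 ± 2.27 M counts (SD, n = 4) in young vehicle, 16.8 ± 2.17 in young dmPGE2, 16.5 ± 1.17 in old vehicle and 16.3 ± 1.34 in old dmPGE2. The full range was 12960704 to 19226963 counts. Totals were higher on date 1 (17.8 ± 0.780 M, SD, n = 8) than on date 2 (14.95 ± 0.852 M, SD, n = 8).

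The largest differences among the libraries lay between the 2 dates, followed by those between the ages. The first principal component of 1000 genes held 55.1% of the variance and separated the dates, and the second held 14.3% and separated the ages. Vehicle libraries of date 2 had far more RNA of mature and committed blood cells. Mpo, a granule enzyme of myeloid progenitors, averaged 5.57 ± 3.67 CPM on date 1 and 1456 ± 734 CPM on date 2 (SD, n = 4 mice each). S100a8, a neutrophil calcium-binding protein, averaged 0.817 ± 0.159 and 155 ± 39.0 CPM. On date 1, 9 of 21 neutrophil markers and 5 of 25 T and NK cell markers passed the filter on low counts. The erythroid list shared Gata1 with the platelet list, and the monocyte list shared Csf1r with the myeloid list. Each age and treatment group held the same number of mice from each date. On date 2 erythroid markers had a mean log2 CPM of 7.17 to 7.31 in young and 5.33 to 6.02 in old libraries. Neutrophil markers had 4.53 to 4.98 and 3.80 to 4.08, and B cell markers overlapped (2.51 to 3.29 and 1.94 to 2.85). The first component on date 2 ran from 57.7 to 62.8 in young and from 28.1 to 36.1 in old libraries. The term for date in the age fits is the same for both ages, so it cannot remove such a difference.

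**Figure D1:**
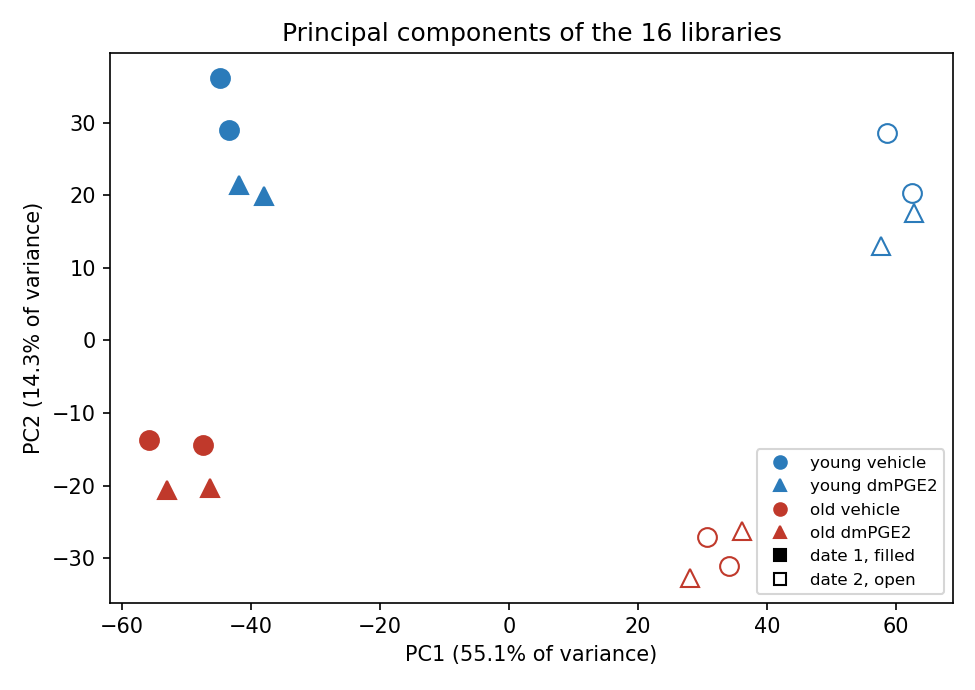
Principal components 1 and 2 of the 16 libraries, with each axis giving its share of the variance, color for age, shape for treatment, and filled symbols for date 1. The dates part along the first axis (55.1% of variance) and the ages along the second (14.3%).

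The first question was what dmPGE2 changes in stem cells of both ages. Over all 8 mice, Crem, Pde4b, Dusp2, Dusp6 and Spry2 rose after 1 hour. Crem, a transcription factor gene induced by cAMP, rose 2.5-fold (log2 1.32 ± 0.19 SE, adjusted p = 0.0142). Pde4b, which breaks cAMP down, rose 1.65-fold (log2 0.72 ± 0.10). Dusp2 and Dusp6, phosphatases that act on MAP kinases, rose 1.33-fold and 1.85-fold, and Spry2, an inhibitor of receptor tyrosine kinase signaling, rose 2.44-fold. Mycn, a growth-promoting transcription factor of the Myc family, was 1.80-fold lower (log2 -0.85 ± 0.14, n = 8 pairs), and Sox18, a vascular transcription factor, 1.83-fold lower (log2 -0.87 ± 0.16).

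In all, 71 genes rose and 14 fell of 13942 tested (edgeR, 8 pairs). Other genes with large rises were Gadd45b (2.33-fold), a stress-induced gene, Zc3h12a (2.19-fold), an RNase that degrades inflammatory mRNA, Dll4 (2.12-fold), a Notch ligand, Sertad1 (1.90-fold) and Lysmd3 (1.87-fold). Tnfaip3, a feedback inhibitor of NF-kB, rose 1.89-fold and was higher in 7 of 8 mice. The named falls also held Hyal2 (1.59-fold), Slfn2 (1.57-fold), Zfp574 (1.42-fold), Lpar6 (1.41-fold), Cited2 (1.37-fold), a transcriptional co-regulator, and Supv3l1 (1.36-fold). Crem lies on chromosome 18 from 3266354 to 3337589, Mycn on chromosome 12 from 12936093 to 12941836, and Nr4a1 on chromosome 15 from 101266846 to 101274794 (mm10). The median absolute log2 change of the 85 called genes was 0.486 in old and 0.520 in young mice. All had the same sign in both ages, which calling genes on the average of the ages favors. The size of the count depended on the libraries of date 1: it was 0 without mouse 477, 2 without 478, 1 without 479 and 5 without 480, against 55 without 483, 83 without 484, 166 without 485 and 119 without 486. Without the replicate block it was 39, DESeq2 called 443, limma-voom 225 and the fit without robust dispersion 144.

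Immediate-early genes, which respond within minutes to a signal, were higher as a group, with a median log2 change of 1.06 (camera adjusted p = 5.13e-27; adjusted p = 0.145 with an estimated correlation). Of 24 tested, 1 was called over all genes and 19 rose when adjusted over the list alone. The cAMP-CREB target genes had a median of 1.02 (adjusted p = 4.53e-23; adjusted p = 0.145 with an estimated correlation), with 4 of 28 called over all genes (Crem, Pde4b, Gem and Hspa5) and 17 adjusted over the list alone. Gem, a small GTPase, rose 1.81-fold and was higher in 7 of 8 mice. Of 23 NF-kB and inflammatory genes 1 rose, and adjusted over the list alone 7 rose and 1 fell (median 0.26, adjusted p = 6.63e-07; adjusted p = 0.136 with an estimated correlation). The heat shock list had 3 of 22 members higher (median 0.08, adjusted p = 2.2e-05; adjusted p = 0.136 with an estimated correlation): Dnajb1 (1.44-fold), Hspa5 (1.43-fold) and Dnajb9 (1.42-fold). Hspa5 and Dnajb9 are chaperones of the endoplasmic reticulum and Dnajb1 is a cytosolic one. The p53 target list had a median of 0.08 (adjusted p = 0.00357; adjusted p = 0.136 with an estimated correlation) with Gadd45b called, and 4 higher and 1 lower adjusted over the list alone. The 48 ribosomal protein genes (median -0.07, adjusted p = 4.02e-05; adjusted p = 0.824 with an estimated correlation) and the 41 oxidative phosphorylation genes (median -0.07, adjusted p = 0.000962; adjusted p = 0.752 with an estimated correlation) were lower as groups, with no single member called over all genes or adjusted over the list alone. Both lists were called on date 1 and not on date 2 (adjusted p = 0.208 and 0.498 there). All 7 list calls were lost with an estimated correlation.

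The prostaglandin receptors showed no called change after dmPGE2. Ptger4, the Gs-coupled EP4 receptor, averaged 85.8 ± 10.5 CPM in young vehicle and 84.0 ± 11 in young dmPGE2, and 204 ± 38.2 and 167 ± 30.8 in old mice (SD, n = 4). Its log2 change over all mice was -0.16 ± 0.08 (adjusted p = 0.415). Ptger1 and Ptger3 changed by log2 0.07 ± 0.09 and -0.00 ± 0.05, and Ptger2 stayed near the detection floor at a group mean of 0.231 to 1.34 CPM. Genes of homing, survival and cycling that were chosen beforehand were also not called. Cxcr4, the homing receptor, had a log2 change of -0.32 ± 0.16 (adjusted p = 0.425), Birc5 (survivin) -0.18 ± 0.08 (adjusted p = 0.373) and Ccnd1 (cyclin D1) -0.01 ± 0.12. Selp, Slamf1 and Vwf, all higher in old mice, had log2 changes of 0.08 ± 0.08, 0.10 ± 0.07 and 0.11 ± 0.06. The remaining lists were not called by camera: prostaglandin genes (0 of 18), cAMP-PKA components (0 of 26), Wnt targets (0 of 13), homing genes (0 of 24), interferon-stimulated genes (0 of 30), cell cycle (0 of 37), apoptosis (0 of 25), platelet (0 of 30), lymphoid (0 of 25), myeloid (0 of 25) and erythroid genes (0 of 16), and markers of neutrophils (0 of 20), monocytes (0 of 25), B cells (0 of 18), T and NK cells (0 of 22) and endothelium (0 of 15). Plscr2 fell among 38 genes known to be higher in aged stem cells (1.35-fold, 7 of 8 mice), and Mycn among 39 stem cell identity genes. Within single dates camera called some of these lists. On date 1 alone prostaglandin genes were called higher (median -0.01, mean 0.33, adjusted p = 0.0258). On date 2 alone erythroid markers were called lower (median -0.13, adjusted p = 1.04e-05) and aged stem cell genes higher (0.10, adjusted p = 0.0115). Neither of the latter was called on date 1 (adjusted p = 0.969 and 0.839).

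The response was much larger on date 1 than on date 2. Nr4a1, an early-induced nuclear receptor, rose 68.7-fold on date 1 (log2 6.10 ± 0.08) and 1.78-fold on date 2 (log2 0.83 ± 0.07), with 4 pairs per date in a fit with a dmPGE2 term for each date and age. Ptgs2 (cyclooxygenase-2) rose 51.2-fold and 2.40-fold, and Fos 3.09-fold and 1.35-fold. Crem rose 3.37-fold on date 1 (adjusted p = 0.000165) and had a 1.87-fold value on date 2 (adjusted p = 0.0893). Cxcr4 fell on date 1 (log2 -0.78 ± 0.14, adjusted p = 0.00944) and had a value of 0.11 ± 0.14 on date 2 (adjusted p = 0.880). Dusp2 rose alike on both dates, by log2 0.40 ± 0.07 and 0.42 ± 0.07. Mycn fell on both, with log2 values of -1.22 ± 0.07 and -0.48 ± 0.07. The dmPGE2 effect differed between dates for 151 genes, 141 of them with the lower signed log2 value on date 2. The 10 with the higher value included genes whose fall was weaker on date 2, such as Mycn and Rsrp1 (log2 -1.25 and -0.48). In vehicle, Nr4a1 stood at 71.0 ± 35.9 CPM on date 1 and 1826 ± 513 on date 2, and in dmPGE2 at 4531 ± 1250 and 3191 ± 483 (SD, n = 4). Over all mice without the date terms, Nr4a1 (log2 3.44 ± 1.39, adjusted p = 0.390), Ptgs2 (2.98 ± 0.91, adjusted p = 0.269) and Fos (1.03 ± 0.27, adjusted p = 0.212) were not called.

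With each date fitted alone, 725 genes were called on date 1 and 51 on date 2. Of the 85 genes called in all mice, 82 were among the first and 6 among the second. Immediate-early genes had a median log2 change of 1.64 on date 1, with 22 of 24 called, and of 0.43 on date 2, with 7 called. The cAMP-CREB targets had medians of 1.44 (18 of 28 called) and 0.49 (11 called). The fit with date terms called 347 genes over all mice, 84 of the 85 among them, and in it the immediate-early list passed with an estimated correlation (adjusted p = 0.000575), as did the cAMP-CREB list (adjusted p = 0.000279). That fit was chosen after seeing the data.

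**Figure D2:**
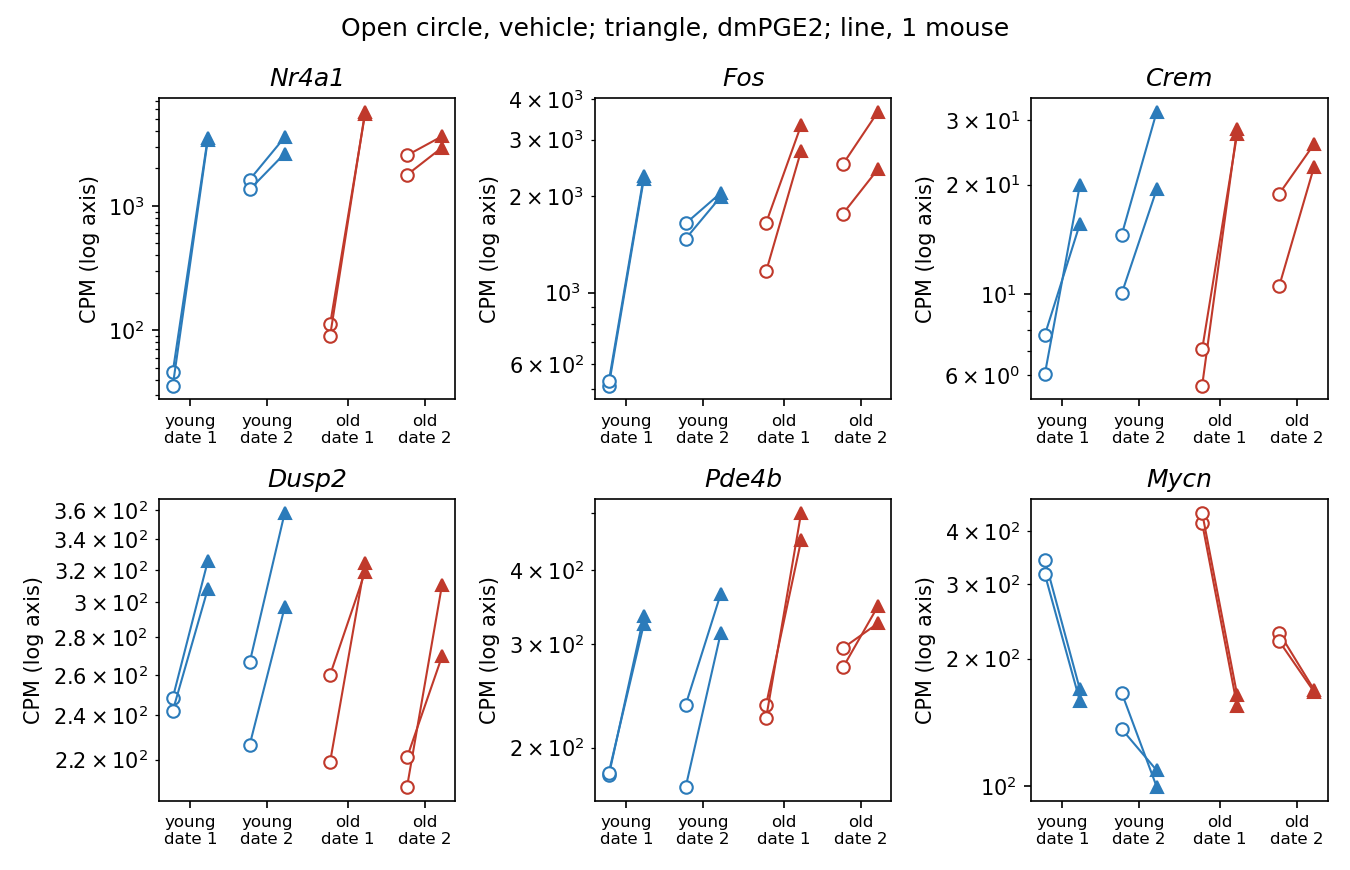
Levels of 6 genes in CPM on a log axis, with an open circle for vehicle and a triangle for dmPGE2 joined per mouse, by age and date. Nr4a1 rises 68.7-fold on date 1 and 1.78-fold on date 2, while Dusp2 rises by log2 0.40 and 0.42.

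In old mice alone, the early genes given here had positive values. Crem had a log2 change of 1.45 ± 0.27, Nr4a1 of 3.19 ± 1.95, Fos of 0.81 ± 0.38 and Ptgs2 of 2.96 ± 1.26 (n = 4 pairs), none of them called. The immediate-early list had a median of 0.95 (adjusted p = 8.86e-19; adjusted p = 0.278 with an estimated correlation) and the cAMP-CREB list one of 0.92 (adjusted p = 7.04e-15; adjusted p = 0.278 with an estimated correlation). NF-kB (median 0.20, adjusted p = 0.00788), p53 (0.07, adjusted p = 0.0451) and heat shock genes (0.10, adjusted p = 5.39e-05) were higher as groups, each with an adjusted p of 0.278 with an estimated correlation. The NF-kB list was not called on date 2 (median 0.07, adjusted p = 0.496). The ribosomal protein list was slightly higher (median 0.05, adjusted p = 0.0466; adjusted p = 0.945 with an estimated correlation) and was not called on date 1 (adjusted p = 0.794). All 6 list calls were lost with an estimated correlation. On date 2 alone camera also called erythroid markers lower (median -0.33, adjusted p = 1.5e-10) and myeloid genes higher (0.04, adjusted p = 0.0199). Neither was called on date 1 (adjusted p = 0.794 and 0.412). edgeR called 0 of 13942 genes, with a smallest adjusted p of 0.147, 1096 genes at an unadjusted p under 0.05 and 697 expected by chance. DESeq2 called 86 higher and 28 lower, and limma-voom 0. With old mice of date 1 alone 373 genes were called and with those of date 2 alone 5, and the fit with date terms called 210.

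In young mice alone, Crem had a log2 change of 1.20 ± 0.27, Nr4a1 of 3.68 ± 1.97 and Fos of 1.25 ± 0.40 (n = 4 pairs), none of them called. The immediate-early list had a median of 1.24 (adjusted p = 1.57e-15; adjusted p = 0.347 with an estimated correlation), the cAMP-CREB list one of 1.24 (adjusted p = 2.54e-14; adjusted p = 0.347 with an estimated correlation) and the NF-kB list one of 0.58 (adjusted p = 1.68e-06; adjusted p = 0.257 with an estimated correlation). The p53 (median 0.15, adjusted p = 0.0311; adjusted p = 0.298 with an estimated correlation) and heat shock lists (0.08, adjusted p = 0.014; adjusted p = 0.347 with an estimated correlation) were also higher, the latter not called on date 1 (adjusted p = 0.139). Lists of growth and energy metabolism were lower. All 48 ribosomal protein genes had values below 0 (median -0.21, adjusted p = 2.26e-17; adjusted p = 0.373 with an estimated correlation), and 33 fell adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.17 (adjusted p = 4.13e-10; adjusted p = 0.373 with an estimated correlation), with 8 lower adjusted over the list alone, and cell cycle genes one of -0.09 (adjusted p = 0.00392; adjusted p = 0.298 with an estimated correlation), not called on date 1 (adjusted p = 0.218). All 8 list calls were lost with an estimated correlation. On date 2 alone camera also called aged stem cell genes (median 0.20, adjusted p = 0.000448) and platelet genes (0.13, adjusted p = 0.00383) higher. Neither was called on date 1 (adjusted p = 0.455 and 0.464). On date 1 alone it called prostaglandin genes higher (median -0.01, mean 0.40, adjusted p = 0.0386). Without the replicate block 5 lists were called. edgeR called 0 of 13942 genes, with a smallest adjusted p of 0.0576 and 1785 genes at an unadjusted p under 0.05. DESeq2 called 192 higher and 85 lower, limma-voom 0, the young libraries alone 25, date 1 alone 477, date 2 alone 25 and the fit with date terms 257. Without mouse 480 it was 2 genes, without 485 1 gene and without 486 4 genes.

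Whether old and young stem cells respond differently was tested by the interaction. edgeR called 0 genes for it, with a smallest adjusted p of 0.357 and 955 genes at an unadjusted p under 0.05. The smallest p belonged to Slfn14 (log2 old minus young -2.85 ± 0.49), Evc (-1.41 ± 0.26) and Mycbp2 (-0.68 ± 0.12), which did not pass. The difference was -0.49 ± 2.86 for Nr4a1, 0.25 ± 0.38 for Crem, -0.44 ± 0.54 for Fos and -0.26 ± 0.15 for Ptger4. Ribosomal protein genes differed as a group by a median of 0.26 (adjusted p = 1.1e-19; adjusted p = 0.943 with an estimated correlation), with 0.32 on date 1 and 0.19 on date 2. Oxidative phosphorylation genes differed by 0.17 (adjusted p = 1.38e-09; adjusted p = 0.943 with an estimated correlation), with 0.26 on date 1 and 0.10 on date 2. Cell cycle genes differed by 0.09 (adjusted p = 0.00126; adjusted p = 0.518 with an estimated correlation), with 0.10 on date 1, where the list was not called (adjusted p = 0.117), and 0.12 on date 2. On date 1 alone the dmPGE2 effect on immediate-early genes was lower in old than in young mice (median difference -0.28, adjusted p = 1.95e-06, 5 of 24 called), although their levels were higher in old mice in both arms, and on date 2 the list was not called (-0.04, adjusted p = 0.828). On date 2 alone the effect was lower in old mice for the cAMP-CREB (median difference -0.25, adjusted p = 0.000163) and NF-kB lists (-0.28, adjusted p = 0.0163), for genes known to be higher in aged stem cells (-0.20, adjusted p = 0.00844) and for platelet (-0.11, adjusted p = 0.0335) and erythroid genes (-0.29, adjusted p = 0.000444), and higher for myeloid genes (0.05, adjusted p = 0.0306), with no single member called over all genes. On date 1 none of these 6 lists was called, and 5 of them had medians of the opposite sign: 0.03 for cAMP-CREB, 0.11 for NF-kB, 0.14 for aged stem cell, 0.16 for platelet and 0.19 for erythroid genes. With date terms, the dmPGE2 effect was lower in old mice for the immediate-early list (median difference -0.20, adjusted p = 0.000674) and the cAMP-CREB list (-0.12, adjusted p = 0.0427), and both were lost at adjusted p = 0.410 with an estimated correlation. DESeq2 called 10 higher and 7 lower, limma-voom 0, date 1 alone 24, the fit with date terms 1, and the fit without mouse 486 called 2.

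The log2 changes of old and young mice correlated at r = 0.166 and rho = 0.138 across the 13942 genes, and 54.4% of the genes had the same sign. Genes are not independent replicates, and no p is given. The correlation was 0.292 on date 1 and -0.00797 on date 2. It was 0.378 under the stricter filter. Leaving out 1 mouse gave 0.0698 without mouse 477, 0.0749 without 479 and 0.0614 without 480.

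Under vehicle, stem cells of old mice differed strongly from those of young mice. Selp (P-selectin) averaged 32.2 ± 15.2 CPM in young and 445 ± 82.3 CPM in old mice (SD, n = 4), a 14.2-fold rise (log2 3.83 ± 0.25). Clca3a1, a chloride channel accessory protein, rose 18.6-fold from 6.49 ± 1.02 to 122 ± 26.8 CPM. Vwf (von Willebrand factor, a platelet adhesion protein) rose 4.45-fold, Nupr1, a stress-induced nuclear protein, 8.58-fold, and Aldh1a1, an aldehyde dehydrogenase, 3.21-fold. In all, 1133 genes rose and 1185 fell of 13369 tested (edgeR, 4 against 4 mice, date as a term). Of 38 genes known to be higher in aged stem cells, 36 rose and all 38 adjusted over the list alone, with a median log2 difference of 2.33 (adjusted p = 4.81e-108; adjusted p = 0.00653 with an estimated correlation). The median was 2.12 on date 1 and 2.49 on date 2.

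Platelet and megakaryocyte genes had 12 of 29 members higher, 13 adjusted over the list alone (median 0.44, adjusted p = 2.18e-11; adjusted p = 0.0544 with an estimated correlation). Itgb3, the integrin beta-3 chain, rose 3.57-fold, and Plek (pleckstrin) 1.98-fold. The platelet list shared 6 genes with the aged stem cell list. Of 39 stem cell identity genes 23 rose, 25 adjusted over the list alone (median 0.44, adjusted p = 4.94e-15; adjusted p = 0.218 with an estimated correlation). They included Slamf1 (CD150, 2.33-fold), Procr (the protein C receptor, 1.93-fold) and Txnip (2.07-fold). Within dates the medians were 0.37 and 0.58 for platelet genes and 0.35 and 0.56 for identity genes on date 1 and date 2. The 8 largest rises among the genes that met the naming rule were in Mab21l2 (93.8-fold), Tdrd9 (76.7-fold), Rorb (66.2-fold), a nuclear receptor, Sbspon (log2 5.49 ± 0.32), Osmr (38.7-fold), the oncostatin M receptor, Aldh3a1 (30.6-fold), Ripk4 (29.9-fold) and C4b (26.9-fold), a complement component. Mab21l2, Rorb, Tdrd9, Osmr, Aldh3a1 and Ripk4 averaged 0.117 to 0.652 CPM in young mice, close to the detection floor, so their folds are imprecise.

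**Figure D3:**
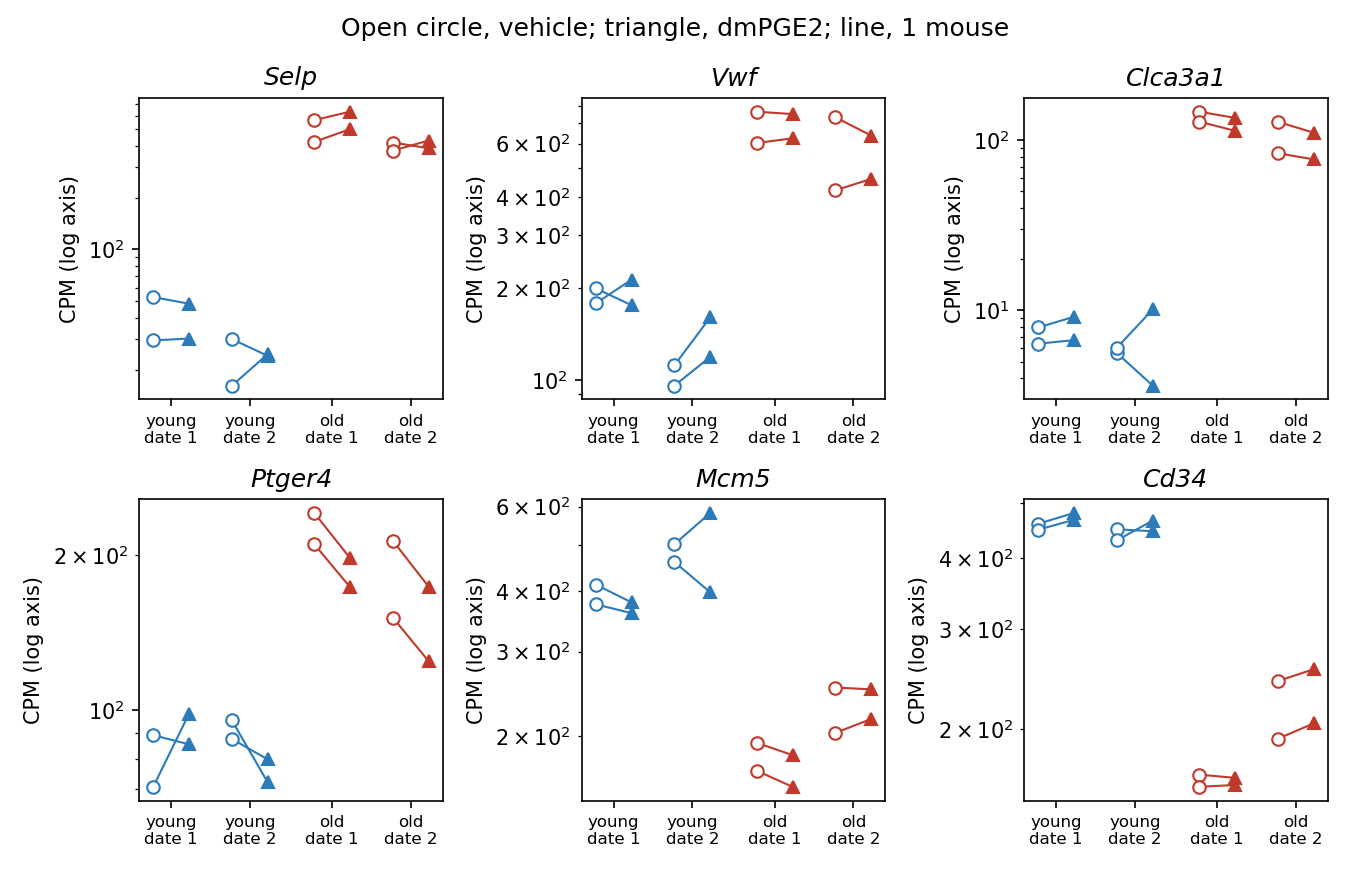
Levels of 6 genes in CPM on a log axis, with an open circle for vehicle and a triangle for dmPGE2 joined per mouse, by age and date. Selp, Vwf, Clca3a1 and Ptger4 are higher and Mcm5 and Cd34 lower in old mice under vehicle, with Selp at 32.2 CPM in young and 445 CPM in old mice.

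Genes of DNA replication and mitosis were lower in old mice. Of 37 cell cycle genes 34 fell and 1 rose, with a median of -0.97 (adjusted p = 1.61e-41; adjusted p = 0.0919 with an estimated correlation). Mcm5, a subunit of the replicative helicase, was 2.15-fold lower (438 ± 54.7 CPM in young and 205 ± 34.8 in old mice, SD, n = 4), Rrm2, a subunit of ribonucleotide reductase, 2.35-fold, Cdc6 2.17-fold and Birc5 2.60-fold. The riser was Ccnd1 (cyclin D1, 1.64-fold). On date 1 the median was -1.03 with 31 members lower, and on date 2 it was -0.87 with 18 lower. Of 41 nuclear genes of oxidative phosphorylation 29 fell, 36 adjusted over the list alone (median -0.30, adjusted p = 1.09e-12; adjusted p = 0.298 with an estimated correlation), Cox5a (1.41-fold) and Ndufa4 (1.40-fold) among them. Its medians were -0.33 and -0.29 on date 1 and date 2. Of 48 ribosomal protein genes, Rpl38 alone fell (list median -0.10, adjusted p = 0.0195; adjusted p = 0.738 with an estimated correlation), and the list was not called on date 1 (adjusted p = 0.148). The 8 largest falls under the same rule were in Rgs7bp (log2 -5.32 ± 0.57), Hnf4a (7.32-fold), Mmp2 (6.65-fold), Il12rb2 (5.32-fold), Socs2 (4.97-fold), a cytokine signaling inhibitor, Shisa8 (4.48-fold), Kcnk12 (3.86-fold) and Rps4l (3.62-fold). Rgs7bp averaged 0.302 CPM in old mice, also close to the floor.

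Myeloid progenitor genes had 10 members lower and 3 higher of 25 (median -0.61, adjusted p = 0.000517; adjusted p = 0.298 with an estimated correlation). Cd34, a progenitor surface protein, was 2.39-fold lower and Ctsg (cathepsin G) 2.39-fold lower, while Prtn3 rose 1.71-fold and Csf3r, the G-CSF receptor, 1.49-fold. Erythroid markers had 6 of 16 lower, 9 adjusted over the list alone (median -0.95, adjusted p = 6.04e-06; adjusted p = 0.311 with an estimated correlation), Rhd (3.54-fold) and Rhag (3.16-fold) among them. Neutrophil markers had 3 of 19 lower (median -0.67, adjusted p = 0.0159; adjusted p = 0.355 with an estimated correlation): Lcn2 (3.86-fold), Cd177 (3.77-fold) and Ngp (2.42-fold). Their median was -0.24 on date 1, where 9 markers were tested and the list was not called (adjusted p = 0.459), and -0.66 on date 2. The myeloid median was -0.01 on date 1 and -0.73 on date 2, and the list was called lower on both (mean -0.42 and adjusted p = 0.0239 on date 1). Cd34 averaged 455 CPM in young and 162 in old mice on date 1, and 440 and 218 on date 2 (n = 2 each). The erythroid median was -0.11 on date 1, where the list was not called (adjusted p = 0.411), and -1.55 on date 2. Between the dates under vehicle, 19 of 25 myeloid genes, 14 of 16 erythroid markers and 16 of 19 neutrophil markers were higher on date 2. Monocyte and dendritic markers were not called as a list over both dates (4 higher and 2 lower of 25; called lower on date 2, adjusted p = 0.0102), although the class II antigen-presentation genes H2-Eb1 (3.94-fold), H2-Aa (2.84-fold) and Cd74 (2.53-fold) rose. B cell (1 higher, Jchain, and 1 lower, Cd37, of 15), T and NK cell (1 of 21 higher, Klrb1c; called lower on date 2, adjusted p = 0.00606) and endothelial lists (1 of 13 higher, Kdr) were not called, nor were lymphoid priming genes (3 higher and 6 lower of 23), in which Satb1 fell 2.26-fold.

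The immediate-early, cAMP-CREB, interferon, NF-kB and p53 lists were called higher in old mice under vehicle, and all of these calls were lost with an estimated correlation. Of 24 immediate-early genes 11 rose, 16 adjusted over the list alone (median 0.72, adjusted p = 1.65e-09; adjusted p = 0.298 with an estimated correlation), with Egr3 5.80-fold, Sgk1 2.88-fold, Egr1 2.05-fold and Fos 1.92-fold higher. The median was 1.09 on date 1 and 0.51 on date 2. The cAMP-CREB targets had 10 higher and 1 lower of 26 (median 0.46, adjusted p = 3.34e-05; adjusted p = 0.298 with an estimated correlation), with Gem 3.14-fold, Nr4a2 2.23-fold and Nr4a1 1.86-fold higher. Crem did not pass (log2 0.06 ± 0.26). Interferon-stimulated genes had 12 of 30 higher (median 0.28, adjusted p = 5.05e-05; adjusted p = 0.337 with an estimated correlation), with Zbp1 2.19-fold and Rtp4 1.82-fold. NF-kB genes had 4 of 23 higher (median 0.38, adjusted p = 0.00613; adjusted p = 0.390 with an estimated correlation), Bcl3 2.40-fold among them. The NF-kB median was 0.72 on date 1 (adjusted p = 2.18e-07) and 0.24 on date 2, where the list was not called (adjusted p = 0.241). Of 22 p53 target genes 7 rose (median 0.27, adjusted p = 0.00256; adjusted p = 0.311 with an estimated correlation), with Gadd45g 4.88-fold and Cdkn1a, the cell cycle inhibitor p21, 2.04-fold higher. Heat shock (2 higher and 2 lower of 22, Hspb1 10.8-fold higher; called higher on date 1, median 0.20 and adjusted p = 0.000729), apoptosis (2 higher and 4 lower of 24), homing (8 higher and 5 lower of 24, with Itga6 1.87-fold higher and Selplg 1.53-fold lower), Wnt (1 higher and 2 lower of 13) and cAMP-PKA lists (4 higher and 1 lower of 26) were not called over both dates.

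Old stem cells had more mRNA of 2 of the 4 prostaglandin E2 receptors. Ptger4 rose 2.36-fold (log2 1.24 ± 0.14, adjusted p = 0.000301) and Ptger3 1.65-fold (log2 0.72 ± 0.10), from 67.5 ± 7.10 to 112 ± 16.1 CPM (SD, n = 4). Ptger1 did not pass (log2 0.12 ± 0.13), and Ptger2 stayed at 1.34 CPM in young and 0.460 CPM in old mice. Slco2a1, the prostaglandin transporter, rose 5.49-fold, and Ptgr1, a prostaglandin reductase, was 2.49-fold lower. Ptgs2 had a log2 difference of 1.74 ± 0.52 (adjusted p = 0.0504). Of the 18 prostaglandin genes 5 rose and 2 fell, and the list was not called (adjusted p = 0.0594). Cxcr4 did not pass (log2 -0.30). The count of 2318 age genes was 971 without the date term, 1092 on date 1 alone, 483 on date 2 alone and 1448 without mouse 480.

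In the dmPGE2 libraries the same 8 mice showed the age difference again, which is not independent of the vehicle comparison. Selp rose 15.5-fold (log2 3.95 ± 0.15), Sdpr (cavin-2) 5.20-fold, Vwf 3.72-fold and Slamf1 2.02-fold. Ptger4 rose 1.99-fold (log2 0.99 ± 0.11), Ptger3 1.65-fold and Ptgs2 2.39-fold. Mcm5 was 2.14-fold, Birc5 2.09-fold and Cd34 2.42-fold lower. In all, 1043 genes rose and 851 fell of 13279 tested (edgeR, 4 against 4 mice). Of 13086 genes tested in both arms, 718 were called higher in both, where independent calls would share 89.1, and 557 lower in both against 76.9, with 0 called in opposite directions by edgeR. The count was 804 without the date term, 2236 on date 1 alone, 264 on date 2 alone, and 1104, 1162 and 1221 without mouse 478, 480 and 484.

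Of 38 genes known to be higher in aged stem cells 37 rose under dmPGE2 (median 2.22, adjusted p = 5.45e-130; adjusted p = 0.00304 with an estimated correlation), with medians of 2.27 on date 1 and 2.16 on date 2. Platelet genes had 13 of 29 higher (median 0.49, adjusted p = 1.88e-15; adjusted p = 0.0440 with an estimated correlation) and stem cell identity genes 19 of 39 (0.39, adjusted p = 3.07e-16; adjusted p = 0.188 with an estimated correlation). Cell cycle genes had 33 lower and 1 higher of 37 (median -0.90, adjusted p = 8.82e-37; adjusted p = 0.0619 with an estimated correlation). Immediate-early genes had 14 of 24 higher (0.75, adjusted p = 5.68e-12; adjusted p = 0.316 with an estimated correlation), with Egr3 3.85-fold and Fos 1.42-fold higher, while Nr4a1 (log2 0.39, adjusted p = 0.0736) and Crem (0.29) did not pass. The prostaglandin list was called here, with 6 higher and 1 lower of 17 (median 0.13, adjusted p = 0.0175; adjusted p = 0.188 with an estimated correlation), Hpgds 2.45-fold higher among them. Ribosomal protein genes had 5 of 48 higher (0.17, adjusted p = 0.000269; adjusted p = 0.624 with an estimated correlation), with a median of 0.25 on date 1, and the list was not called on date 2. Oxidative phosphorylation genes had 6 of 41 lower (-0.13, adjusted p = 0.000662; adjusted p = 0.482 with an estimated correlation) and were not called on date 1 (adjusted p = 0.0771).

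Further lists under dmPGE2 were called and then lost with an estimated correlation. These were cAMP-CREB targets (9 of 28 higher, adjusted p = 0.000499, and adjusted p = 0.482 with an estimated correlation), interferon-stimulated genes (9 of 30 higher, with the same adjusted p values), NF-kB genes (6 higher and 2 lower of 23, 0.0447 and 0.602), p53 targets (7 higher and 1 lower of 22, 0.000269 and 0.252), myeloid progenitor genes (2 higher and 9 lower of 25, 0.00251 and 0.240), erythroid markers (6 of 16 lower, 6.2e-06 and 0.422) and neutrophil markers (3 of 18 lower, 0.0475 and 0.316). Several of these calls rested on 1 date. NF-kB genes had a median of 0.87 on date 1 (12 of 22 higher, adjusted p = 4.58e-09) and of -0.11 on date 2 (0 of 24 called, adjusted p = 0.700). The cAMP-CREB median was 0.62 on date 1 (17 of 28 higher, adjusted p = 4.25e-24) and 0.02 on date 2 (0 of 28 called, adjusted p = 0.373). Myeloid and neutrophil lists were not called on date 1 (adjusted p = 0.209 and 0.360). Flt3, a cytokine receptor of lymphoid and myeloid progenitors, was 3.43-fold lower, and Csf1r 1.92-fold lower. The erythroid list was not called on date 1 and had a median of -1.90 on date 2, on which 12 of 16 erythroid markers were higher than on date 1 under dmPGE2. By the naming rule, the largest rises after Kcnb2, which was close to 0 CPM in young mice, were in Sbspon (39.7-fold), Tdrd9 (36.6-fold), Mab21l2 (32.9-fold), Osmr (27.3-fold), Matn4 (26.4-fold), Spon1 (25.3-fold) and Dnm3 (24.6-fold), and of these Mab21l2, Spon1, Osmr, Dnm3 and Tdrd9 averaged 0.342 to 0.757 CPM in young mice, close to the floor. The largest falls by that rule were in Rgs7bp (22.8-fold, to 0.426 CPM in old mice), Mmp2 (7.49-fold), Hnf4a (5.40-fold), Synpo2 (4.59-fold), Myh10 (4.29-fold), Cd86 (4.24-fold), Sec16b (4.15-fold) and Socs2 (4.09-fold). Not called as lists were cAMP-PKA (5 higher, 1 lower of 26), Wnt (1 higher, 2 lower of 11), homing (9 higher, 5 lower of 24), apoptosis (2 higher, 3 lower of 25), heat shock (3 higher, 1 lower of 22; called higher on date 1, median 0.35 and adjusted p = 1.08e-06) and lymphoid genes (2 higher, 6 lower of 22), and markers of monocytes (4 higher, 2 lower of 25), B cells (2 of 15 lower; called lower on date 2, adjusted p = 0.0162), T and NK cells (1 higher, 2 lower of 21; called lower on date 2, adjusted p = 0.00656) and endothelium (1 of 13 higher).

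The last question was whether dmPGE2 moves the expression profile of old stem cells toward that of young ones. A negative shift would mean a move toward the young profile and a positive shift one toward the old profile. In old mice the mean shift was 0.0203 ± 0.0590 (log2, SD, n = 4 mice), with 2 of 4 below 0 (exact sign-flip permutation test, two-sided, p = 0.5). Its sign in old mice followed the date. It was 0.0615 (479) and 0.0797 (480) on date 1, and -0.0387 (485) and -0.0214 (486) on date 2. In young mice the mean shift was 0.255 ± 0.114 with 0 of 4 below 0 (exact permutation p = 0.125, the smallest that 4 mice allow). Over all 8 mice it was 0.138 ± 0.151 (exact permutation p = 0.03125), with 0.138 on date 1 and 0.137 on date 2. Ranked in the dmPGE2 libraries of the other date, it was 0.0895 in old mice with 1 of 4 below 0 (exact permutation p = 0.25). By that ranking it was 0.268 in young mice (exact permutation p = 0.125). With the fixed list of genes known to be higher in aged stem cells in place of the ranked genes, chosen after seeing the data, it was 0.0881 in all mice (exact permutation p = 0.375) and -0.0124 in old and 0.189 in young mice (exact permutation p = 0.75 and 0.375). The young mice had 0.0162 (477) and -0.0530 (478) on date 1, and 0.295 (483) and 0.496 (484) on date 2. Without early response genes, also chosen after seeing the data, the shift was -0.0600 in old mice with 4 of 4 below 0 (exact permutation p = 0.125), 0.194 in young mice (exact permutation p = 0.125) and 0.0667 in all mice (exact permutation p = 0.336). Those genes were partly taken from the calls for dmPGE2 in the same libraries. Without mouse 486 the values were 0.369 in old, 0.502 in young and 0.445 in all mice. There the mice of date 1 ran from 0.570 to 0.782, with their genes ranked against 485 as the only old library. The values of the date 2 mice hardly changed. The shift of all mice lost its call without mouse 477 (0.122), 479 (0.144), 480 (0.162), 483 (0.141), 484 (0.132) or 485 (0.129), and in old mice the mean was negative without 477 (-0.00802), 479 (-0.0214), 480 (-0.00195) or 484 (-0.0112).

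**Figure D4:**
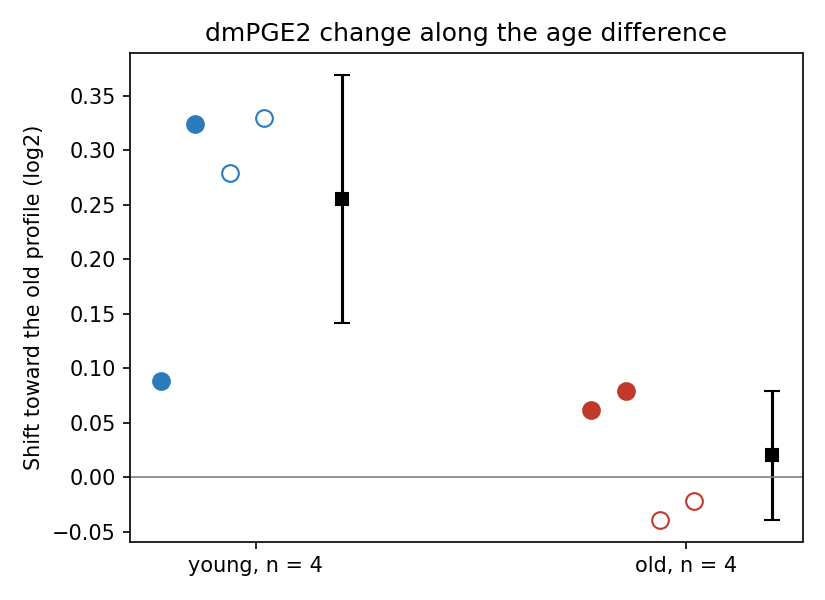
Shift of each mouse along the age difference on the log2 scale, with filled symbols for date 1, open symbols for date 2, and a square with SD for the mean of 4 mice. All 4 young mice lie above 0 with a mean of 0.255. The old mice have a mean of 0.0203, and those of date 1 lie above 0 and those of date 2 below 0.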

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

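The tests of dilution and of exchanged libraries, the fit with a dmPGE2 term for each date, the lists within each date and the splits within dates for the shift were chosen only after the results they bear on were seen.

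The dmPGE2 effect differed between the dates for 151 genes, and the 177 genes that rose at least 2-fold on date 1 had median changes of 1.77 to 1.96 (log2) in the mice of date 1 and of 0.337 to 0.613 in those of date 2. Choosing genes by their rise on date 1 favors a larger change and a lower vehicle level on that date. The tables argue against lower depth, since 159 genes differed after all libraries were thinned to the lowest total, against dilution by RNA of other cells, since the gain in CPM on date 2 was a median of 0.323 of that on date 1 (quartiles 0.182 and 0.411) where stem cell identity genes kept 0.784 (0.726 and 0.853) and the immediate-early list, not chosen on date 1, had a median gain of 0.374 (0.244 and 0.452), and against exchanged vehicle and dmPGE2 libraries, since the lowest median change of a date 2 mouse was 0.337 and all 4 lay above 0. Chance is argued against by a fit without age terms, in which the split by date gave 138 genes where the fit with age terms gave 151. Of 35 splits of the mice, 1, the one by date, reached 138, and the highest other gave 0. That is the smallest share that 35 splits allow. What stays open is a higher level before dmPGE2: in vehicle 170 of the 177 genes were higher on date 2, with a median of 11.8 CPM on date 1 and 36.5 on date 2, while the dmPGE2 medians were 52.4 and 49.4, and 22 of 24 immediate-early genes were higher on date 2 in vehicle by mean CPM. A candidate explanation is that handling on date 2 may already have induced these genes, which no library here tests, and a difference between the mice of each date also stays open.

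The vehicle libraries of date 2 held more RNA of neutrophils (16 of 19 markers higher, median log2 7.60), T and NK cells (17 of 21, 7.34), erythroid cells (14 of 16, 3.58) and B cells (9 of 15, 2.91), in cells that the labels describe as sorted stem cells, and Mpo, Prg2 and S100a8 reached 1456, 1484 and 155 CPM. The neutrophil median was 7.27 after thinning. Thinning keeps CPM the same on average, so this value cannot decide on lower depth on date 2. RNA of 1 mixed source in varying amount stays open, since the differences between the lists varied 0.850 times as much as the lists themselves. The lower cell cycle genes of old mice stood on date 1 alone (median -1.03 against -0.97 pooled), which argues against RNA of other cells on date 2 as their cause, and so did the higher immediate-early genes (1.09 against 0.72). The erythroid markers had a median near 0 on date 1 (-0.106 against -0.95 pooled) and were not called there, which is consistent with RNA of other cells on date 2 as their source, whereas for the myeloid progenitor genes this stays open, since their median was -0.00841 on date 1 against -0.61 pooled but members went both ways, the list was still called lower (mean -0.42, adjusted p = 0.0239) and Cd34 was lower in old mice on both dates. A difference in cell composition between old and young marrow stays open as well and was not tested.

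Some measures of the response differed between old and young mice by the preset list test: the list medians of old minus young were 0.0945 for cell cycle genes, 0.258 for ribosomal protein genes and 0.172 for oxidative phosphorylation genes. All 3 calls were lost with an estimated correlation, where the smallest adjusted p was 0.518, and with fry, where it was 0.332. On date 1 alone 24 genes had an effect that differed between the ages (10 higher and 14 lower in old mice), while the fit with date terms gave 5 on date 1 (2 higher and 3 lower) and 0 on date 2, with a smallest adjusted p of 0.180 there and 1063 genes at an unadjusted p under 0.05 by edgeR. For the interaction over all libraries, 35 of 35 splits of the mice gave at least as many genes as the real 0. Any split must reach 0, so this cannot decide on chance. The highest other split, which follows the dates, gave 138 and so points to that structure of the samples. The shift along the age difference was -0.235 for old minus young mice (exact permutation p = 0.0286 over 70 splits, which ignore date). Over the 36 splits within dates it was not past the threshold (exact permutation p = 0.0556, the smallest that they allow). Without mouse 486 the shifts were 0.369 in old and 0.502 in young mice, and their difference was not tested again. The rise came from the mice of date 1, whose genes were then ranked with 485 as the only old library.

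Chance is argued against for the other main counts. For dmPGE2 in all mice 1 of 100 splits, the real one, reached 85 genes, with a highest other of 4. For age, 1 of 34 splits reached the count under vehicle (2318, highest other 0) and 1 of 34 under dmPGE2 (1894, highest other 4), where the split that follows the dates could not be fitted. That is the smallest share that 34 splits allow. In the other splits a real age difference adds to the spread, which lowers their counts. In old and in young mice alone, 8 of 8 splits each reached the real 0, as any split must, with a highest other of 2 and 1. These splits are also too few for a share under 0.05.

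Single libraries stood far from the other 3 of their group in 5 of 114 tests, where 5.7 are expected by chance. The ribosomal precursor transcript Rn45s took 0.542% of counts in young vehicle mouse 478, against 0.683% to 0.702% in the others. Genes with a count numbered 13991 in young dmPGE2 mouse 483, against 14284 to 14328. They numbered 13851 in old dmPGE2 mouse 485, against 14160 to 14205. Ptgs2 stood at 113 CPM in young dmPGE2 mouse 483, against 69.5 to 73.7. Ptger2 stood at 0.923 CPM in old dmPGE2 mouse 486 and had no count in the others. Principal components were not among these tests. On the third (4.72% of variance) old dmPGE2 mouse 485 stood at -45.4, and all other libraries lay between -7.90 and 23.6.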

How the results depend on the processing

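The fit with a dmPGE2 term for each date and age, the values of the correlation, the shift and the lists within dates, the splits within dates, and the aged stem cell list and the left-out gene sets in the shift were chosen after seeing the data. The cause of the changes below was not tested, except that a date alone and a left-out mouse have fewer samples and the stricter filter tests fewer genes. Under DESeq2 size factors, no filter, the stricter filter and thinning, the counts for dmPGE2, the interaction and age stayed within 1.5 times their value, with 2212 to 2272 genes for age under vehicle, where the Wald test of DESeq2 gave 2856. All 85 genes called in all mice were called by DESeq2, 84 with its size factors, 84 without a filter, 78 with the stricter filter, 81 by limma-voom, 76 after thinning and 29 without the replicate block.

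The Wald test of DESeq2 gave 114 genes in old mice, 277 in young mice, 443 in all mice and 17 for the interaction. limma-voom gave 225 and dispersion without the robust option 144 in all mice. Date 1 alone gave 373 in old, 477 in young and 725 in all mice, 24 for the interaction, 1092 for age under vehicle and 2236 under dmPGE2. Date 2 alone gave 5, 25 and 51 for dmPGE2, 483 for age under vehicle and 264 under dmPGE2. The fit with date terms gave 210, 257 and 347, and 1 for the interaction. Young libraries alone gave 25. Without the date term, age gave 971 under vehicle and 804 under dmPGE2. Without the replicate block all mice gave 39, and the counts of old mice, young mice and the interaction stayed at 0. The correlation of old and young effects was 0.378 with the stricter filter, 0.292 on date 1 and -0.00797 on date 2, where rho was 0.0187 and 50.6% of the genes had the same sign. The shift of old mice was 0.0895 when ranked in dmPGE2 libraries and -0.0600 without early response genes, where that of all mice was 0.0667 (exact permutation p = 0.336). The shift of all mice was 0.151 with 50 genes per direction (exact permutation p = 0.0625), 0.0881 with the aged stem cell list (exact permutation p = 0.375), 0.138 on date 1 (exact permutation p = 0.125) and 0.137 on date 2 (exact permutation p = 0.5). The shift of old minus young mice stayed at -0.235 and lost its call over splits within dates (exact permutation p = 0.0556).

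Leaving out each mouse in turn gave 0 to 0 genes in old mice, 0 to 4 in young mice, 0 to 166 in all mice, 0 to 2 for the interaction, 1448 to 2129 for age under vehicle and 1104 to 2167 under dmPGE2. It gave a correlation of 0.0614 to 0.175 and shifts of -0.0214 to 0.369 in old mice, 0.174 to 0.502 in young mice and 0.102 to 0.445 in all mice.

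Called lists went from 6 in old mice to 0 with an estimated correlation and 1 with fry, from 8 in young mice to 0 with either and 5 without the replicate block, from 7 in all mice to 0 with an estimated correlation, from 3 for the interaction to 0 with either, 9 on date 2 alone and 5 with date terms, from 14 for age under vehicle to 1 and from 15 under dmPGE2 to 2 with an estimated correlation. With fry, the lists called for age under vehicle held except NF-kB (adjusted p = 0.0589), neutrophil (0.0606) and ribosomal protein lists (0.256). Under dmPGE2 they held except cAMP-CREB (0.0866), interferon (0.0593), NF-kB (0.180), erythroid (0.0593) and ribosomal protein lists (0.144). Among values of named genes under the alternatives, for dmPGE2 in all mice 533 kept their side of the threshold, 153 lost their call and 15 gained one. For age under vehicle these were 1882, 177 and 5, and under dmPGE2 1805, 230 and 5. Depth limits genes near the floor of 0.156 to 0.231 CPM, such as Ptger2, and at these sizes simulated 1.5-fold changes were recovered in 71.6% of genes for all mice and 17.9% for the interaction. The simulated changes did not vary between mice or dates as the measured ones did, so these shares may be too high.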

Other observations

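Several gene groups other than cell markers differed between the dates in vehicle libraries. Immediate-early genes were higher on date 2 in 20 of 24 members (median log2 1.43, adjusted p = 1.23e-29; adjusted p = 0.0464 with an estimated correlation), and cAMP-CREB targets in 16 of 26 (0.92, adjusted p = 0.0254 with an estimated correlation). Dusp5, a MAP kinase phosphatase, rose 15.9-fold from 16.9 ± 2.52 to 270 ± 82.4 CPM, and Hes1, a Notch target, 9.60-fold from 21.9 ± 12.7 to 194 ± 88.7 CPM (SD, n = 4 mice per date). Cell cycle genes were higher in 25 of 37 (0.56, adjusted p = 0.156 with an estimated correlation). Stem cell identity genes were lower in 21 of 39 (-0.39, adjusted p = 0.130 with an estimated correlation), with Hlf at 511 ± 53.8 CPM on date 1 and 384 ± 40.1 on date 2 and Procr at 202 ± 58.6 and 145 ± 67.7. Mycn was lower by log2 -1.02 ± 0.08. In dmPGE2 libraries the immediate-early list was not called between the dates (median 0.01, adjusted p = 0.750), and Hes1 stood at 672 ± 334 and 497 ± 156 CPM. In all, 1069 genes were higher and 403 lower on date 2 under vehicle, and 1018 and 538 under dmPGE2. The named genes were chosen after their values were seen.

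Beyond the genes of the report, the fit with date terms had Hes1, Socs3, Vegfa, Klf4 and Cdkn1a among the rises of smallest p after dmPGE2, chosen after seeing the data. Hes1 rose by log2 5.0 ± 0.11 on date 1 and 1.41 ± 0.09 on date 2 (4 pairs each). Socs3, an inhibitor of cytokine signaling, rose by 3.29 ± 0.08 and 0.58 ± 0.07, and Vegfa, a vascular growth factor, by 3.74 ± 0.13 and 0.94 ± 0.11. Klf4 rose by 5.37 ± 0.17 and 1.35 ± 0.13, and Cdkn1a, the cell cycle inhibitor p21, by 3.98 ± 0.11 and 1.06 ± 0.09. Rsrp1 was lower by log2 -1.25 ± 0.06 and -0.48 ± 0.06. On date 1, Fos rose by 2.13 ± 0.07 in young mice and 1.13 ± 0.07 in old mice, a difference of -1.0 ± 0.09 (adjusted p = 0.00348), from a vehicle level that was higher in old mice. On date 2 that difference was 0.13 ± 0.09 (adjusted p = 0.780).

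The shift of young mice toward the old profile under dmPGE2 (0.255, n = 4) may partly reflect early response genes that are both higher in old mice and raised by dmPGE2. Without these genes it was 0.194 (SE 0.0713), from the same mice. It fell from 0.0883 to 0.0253 in mouse 477, from 0.325 to 0.275 in 478 and from 0.279 to 0.131 in 483. In mouse 484 it went from 0.330 to 0.343, so the size of this part stays open in young mice. In old mice the same step took the shift from 0.0203 to -0.0600, with 4 of 4 mice below 0. The genes left out were partly called for dmPGE2 in the same libraries, so this value is not independent of the change it measures. Without the listed cell cycle, ribosomal protein and oxidative phosphorylation genes the shift of young mice was 0.244, so it depended little on these list members. The change of the age-up genes stayed the same in every mouse, and next-ranked genes filled the age-down set. The step therefore cannot decide on these processes as a cause.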
